A study of Aspergillus glaucus with 6 samples.

How the data were processed

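Gene expression was measured by RNA sequencing of mycelium of Aspergillus glaucus CCHA, a salt-tolerant filamentous fungus, grown in medium with added sodium chloride (NaCl). Per the labels' protocols, mycelium was collected on filter paper under vacuum and frozen in liquid nitrogen, RNA was extracted with TRIzol and purified further on RNeasy columns, and libraries were made by standard Illumina methods. The labels place the 6 libraries in 6 conditions: 1 M and 3 M NaCl for 36 h, and 0 M, 1 M, 3 M and 4 M NaCl for 84 h. They give these times as the length of treatment, called culture time here. Any growth before the treatment is not part of these treatment labels. Each condition has 1 library, so the spread between cultures is unknown.

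The deposited files hold raw read counts per gene, 1 file per library, with no normalization by the authors. TopHat2 2.0.8b and HTSeq 0.5.4p2 are named in the submitters' processing notes. The genome build, the gene annotation, the strand setting and the filters are not given in the sources used here. The smallest count in any file is 1, so a gene that a file does not list was taken as having 0 reads in that library. Across the files 8441 gene IDs are listed, of which 7889 have a read in all 6 libraries. The ID numbers run up to 8551, and 110 of these numbers are listed in no file. No file holds a line without a gene ID. Library totals run from 16371771 to 18376857 counts, and 3 counts correspond to between 0.155 and 0.185 CPM (counts scaled to library size), which is the limit that a count of 0 allows. Intervals and floors given here cover counting error only. Reads without molecular identifiers are not independent molecules.

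The files do not pair the gene IDs with gene names. A table of 11428 RefSeq genes of another strain, CBS 516.65 (assembly Aspgl1), was searched by gene ID, locus tag, symbol, synonym and accession, and 0 of the IDs matched. Genes are therefore given by their IDs. The 18 gene lists fixed before the data were examined (osmostress signalling, glycerol and other polyols, trehalose, cation transport, oxidative stress, heat shock proteins, cytosolic ribosomal proteins, ergosterol and membrane lipids, cell wall, conidiation, sexual development, secondary metabolism, sugar transport, glycoside hydrolases, tricarboxylic acid cycle, glycolysis, histones and replication, and proline with related amino acids) could not be matched to IDs and gave no result. Markers of spore-bearing cells and fruiting bodies were among them, so the mix of cell types in each culture was not assessed. Gene positions were not analysed here. Paralogs, overlapping genes and antisense partners could not be recognised, and the counts of such genes are uncertain.

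Library sizes were scaled by TMM factors over all 6 libraries (edgeR 4.0.16 in R 4.3.3). Fold changes between 2 libraries are on the log2 scale with a prior count of 2 per library, scaled to library size. A gene entered a comparison with a TMM-scaled CPM of at least 10 in at least 1 of its 2 libraries. With 1 library per condition no p-value was computed. Genes were instead counted by a fixed rule of size, at least 4-fold, and the counting error of single ratios was given as an exact 95% interval (Clopper-Pearson, SciPy 1.17.1). The named genes are the 2 IDs furthest above and the 2 furthest below in 4 M against 0 M at 84 h, among 4-fold genes whose exact interval excludes 2-fold. The 8 comparisons, the size rule, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named below as added.

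Comparisons that share a library share its chance values. Fold changes were therefore correlated and overlapped only between comparisons with no library in common, over genes with a CPM of at least 10 in at least 1 of the 4 libraries for correlations, and in both comparisons for overlaps. There are 13 such pairs of comparisons and all were computed, 4 of them planned. An overlap is given beside the number that independent lists of the same sizes would share. Genes are not independent replicates, and these correlations across genes carry no p-value. The genes 4-fold apart at 36 h were also followed in the 84 h libraries, all members included. Their median log2 fold change is given with its 95% order-statistic interval over genes and set against 10000 random lists of the same size matched on mean expression. This follow-up was chosen after the data were seen.

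The size rule was tested on simulated data for each of the 8 comparisons, with between 6072 and 6220 genes and Poisson counts drawn from the real means and library sizes. In each of the 8, 100% of genes changed 8-fold and 100% of those changed 16-fold were recovered, 0% of genes changed 2-fold were called, and 0 unchanged genes were called. The simulation holds counting error only, not differences between cultures. It kept genes with a mean CPM of at least 10 over the 2 libraries, for which counting error alone could hardly give another outcome. Genes with a lower mean and changes beyond 16-fold were not simulated. It therefore checks the calculation and not the error rate of the rule on real cultures.

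Alternatives were DESeq2 1.42.0 size factors, total counts without TMM, no low-count filter, a 2-fold threshold, a prior count of 0.5, and a counting interval wholly beyond 4-fold. For correlations they were no filter, a CPM minimum of 50, a prior count of 0.5, and Spearman's rho. TMM factors from only the 2 libraries compared were added after seeing the data. No count model was fitted, since edgeR and DESeq2 served only for scaling.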

Results

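The data are 6 RNA sequencing libraries of Aspergillus glaucus CCHA mycelium, 1 per condition, that cover 2 treatment times (called culture times here) and 4 NaCl concentrations. At 36 h the cultures were in 1 M and 3 M NaCl, and at 84 h in 0 M, 1 M, 3 M and 4 M NaCl. Total counts were 16987222 (1 M, 36 h), 17933754 (3 M, 36 h), 16371771 (0 M, 84 h), 18110271 (1 M, 84 h), 18376857 (3 M, 84 h) and 18009549 (4 M, 84 h), and between 8138 and 8282 genes had a read. The number of genes at a TMM-scaled CPM of 10 or more was 5681 in the 4 M library at 84 h and 5710 in the 3 M library at 36 h, against 6072 to 6116 in the other 4. The 100 most abundant genes took 29.05% of counts in the 4 M library at 84 h and 31.9% in the 3 M library at 36 h, against 24.03% to 26.6% in the others. The widest exact (Clopper-Pearson) 95% interval of any share of counts given here spanned 0.043 percentage points. There are no replicates, so each difference is between 2 libraries, was not set against a spread between cultures, and carries no p-value. The gene IDs could not be paired with gene names, so genes are described by ID and by group.

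The 3 M library at 36 h and the 4 M library at 84 h were the most alike of the 15 pairs of libraries. Across genes, their log2 CPM values correlated at Pearson r = 0.946, and 140 genes differed at least 4-fold between them, of 5908 compared. The next closest pairs were 1 M at 36 h with 0 M at 84 h (r = 0.897, 261 genes) and 1 M at 36 h with 3 M at 84 h (r = 0.886, 276 genes). By the number of 4-fold genes the most distant pair was 3 M at 36 h with 1 M at 84 h (r = 0.633, 1213 genes), and by r it was 1 M with 4 M at 84 h (r = 0.627, 1147 genes). The first principal component of log2 CPM held 63.8% of the variance. On it 3 M at 36 h (77.0) and 4 M at 84 h (89.5) had positive scores, while the other 4 libraries lay between -63.6 and -27.3. The 3 M library at 84 h thus sat on the side of the 0 M and 1 M libraries.

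**Figure D1:**
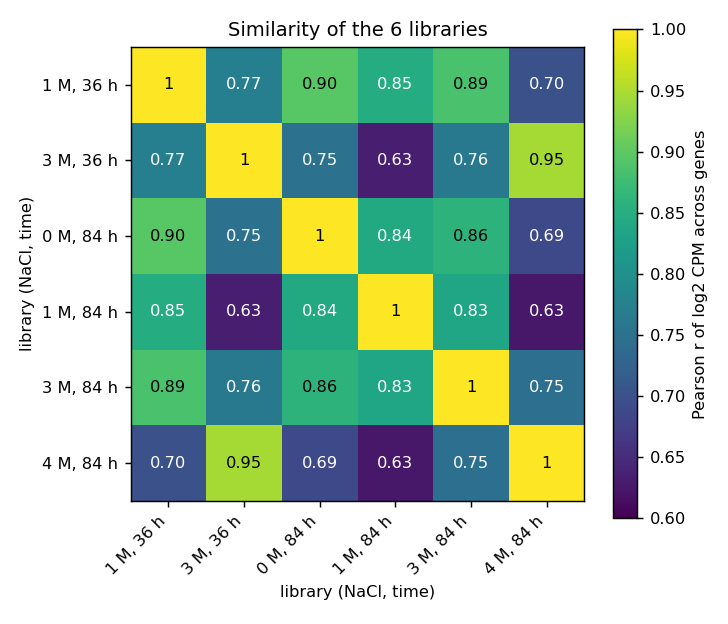
Pearson correlation of log2 CPM across genes for each pair of the 6 libraries, with NaCl concentration and culture time on both axes and r as colour and number. The pair of 3 M at 36 h and 4 M at 84 h reaches 0.95, while their values against the other 4 libraries lie between 0.63 and 0.77.

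The comparison of 4 M with 0 M NaCl at 84 h asked which transcripts differ between the most saline culture and the culture without added salt. Of 6391 genes compared, 638 were at least 4-fold lower and 207 at least 4-fold higher in 4 M. The lower genes were also the more extreme: 274 were at least 16-fold lower and 102 at least 64-fold lower, against 51 and 16 on the higher side. Together the 638 lower genes took 16.9% of counts in the 0 M library and 1.05% in the 4 M library. The 207 higher genes took 1.52% and 9.64%. Of the lower genes, 5 had no read in the 4 M library, where 3 counts correspond to 0.167 CPM. At 84 h the median log2 fold change over all genes compared was 0.11, and 69.9% of genes differed less than 2-fold.

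The genes furthest apart in this comparison went from near the detection limit to high abundance, or the reverse. AG04473.1 had 4 counts in the 0 M library and 14369 in the 4 M library, a log2 fold change of 11.18 (exact 95% counting interval 10.40 to 13.63). AG04474.1, the next ID in the numbering, had 16 and 20416 counts, a log2 fold change of 10.10 (9.56 to 11.07). AG00699.1 stood at 3677 CPM in 0 M and 1 CPM in 4 M, from 63609 and 18 counts (log2 fold change -11.69, interval -12.60 to -11.18). AG07930.1 stood at 936 CPM in 0 M and 0.39 CPM in 4 M, from 16200 and 7 counts (log2 fold change -10.86, interval -12.55 to -10.19). In the 3 M library at 84 h all 4 had intermediate levels: 6.11 CPM for AG04473.1, 26.7 CPM for AG04474.1, 112 CPM for AG00699.1 and 22.3 CPM for AG07930.1. In 1 M at 84 h, AG04473.1 (0.562 CPM) and AG04474.1 (0.899 CPM) were still near the detection limit, whereas AG00699.1 (257 CPM) and AG07930.1 (81.4 CPM) were already below their 0 M levels.

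**Figure D2:**
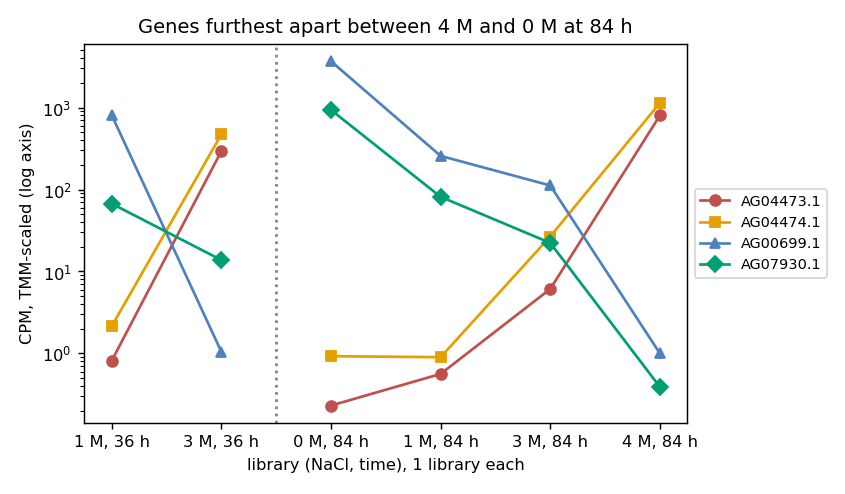
TMM-scaled CPM, on a log axis, of the 2 genes furthest above and the 2 furthest below in 4 M against 0 M at 84 h, in each of the 6 libraries (1 library per point, no error bars). AG04473.1 and AG04474.1 reach 293 and 469 CPM in 3 M at 36 h and 800 and 1137 CPM in 4 M at 84 h, while AG00699.1 is at 1.05 and 1 CPM in those libraries.

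At 84 h, 3 M and 1 M each gave fewer genes 4-fold apart from 0 M (362 and 474) than 4 M did (845). The number did not rise steadily with salt, since it was larger in 1 M than in 3 M. In 3 M, 206 genes were at least 4-fold lower and 156 higher, of 6405 compared, and 81.6% of genes differed less than 2-fold. In 1 M, 292 genes were at least 4-fold higher and 182 lower, of 6429. The excess of higher genes in 1 M depended on the threshold, since at 2-fold 767 genes were higher and 784 lower. Between 3 M and 1 M, 295 genes were 4-fold lower and 164 higher in 3 M. The step from 3 M to 4 M was larger, with 573 genes lower and 147 higher in 4 M, of 6308 compared. Of the 638 genes lower in 4 M than in 0 M, 443 had their largest decrease between 3 M and 4 M, 99 between 1 M and 3 M, and 96 between 0 M and 1 M. The 207 higher genes divided likewise, with 113 at the step from 3 M to 4 M, 49 from 1 M to 3 M and 45 from 0 M to 1 M. The fold changes of the first step (1 M against 0 M) and of the last step (4 M against 3 M), which share no library, correlated weakly and negatively across 6668 genes (r = -0.12, Spearman's rho = -0.27).

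**Figure D3:**
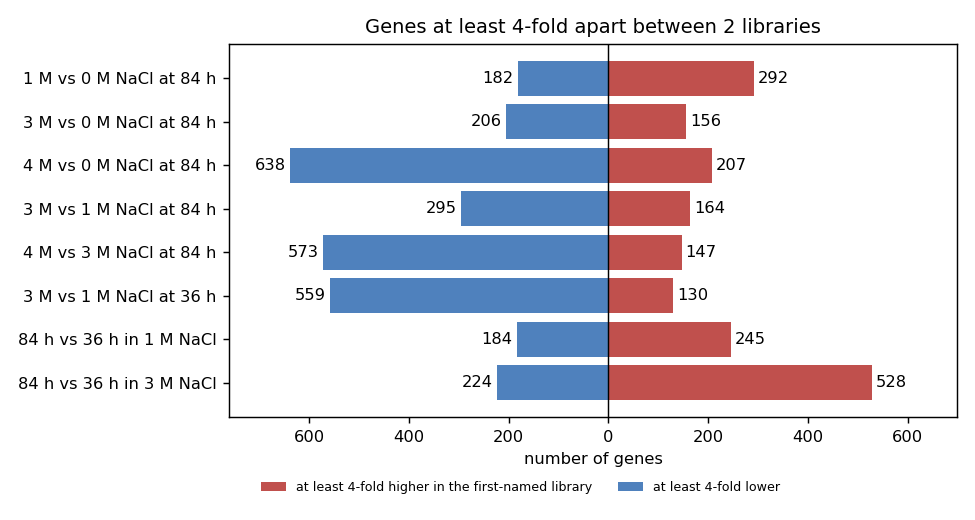
Number of genes at least 4-fold higher (right) and at least 4-fold lower (left) in the first-named library of each of the 8 comparisons, with 1 library on each side. Lower genes outnumber higher genes most in the 3 comparisons with 638, 573 and 559 lower genes, and higher genes outnumber lower ones most for 84 h against 36 h in 3 M (528 against 224).

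A part of the genes 4-fold apart between 4 M and 0 M at 84 h followed the salt concentration step by step. Of the 638 lower genes, 173 (27.1%) were lower at each step from 0 M to 1 M, 3 M and 4 M, and of the 207 higher genes, 74 (35.7%) were higher at each step. The same count was made with the other libraries reordered and 4 M kept last, which gives 6 orders. For the lower genes, 3 of the 6 gave at least 173, the label order included, and the highest was 244, with 0 M and 1 M exchanged. For the higher genes, 3 of the 6 gave at least 74, and the highest was 161. Each order sets its own first library for the 4-fold rule, so these counts do not test the salt order.

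At 36 h, 3 M was compared with 1 M NaCl, since no culture without salt was among the 36 h libraries analysed. In 3 M, 559 genes were at least 4-fold lower and 130 at least 4-fold higher, of 6339 compared. Of the lower genes 58 were at least 64-fold lower, against 4 that were as much higher. The lower genes took 13.7% of counts in the 1 M library and 1.14% in the 3 M library. AG04473.1 and AG04474.1 had the largest positive log2 fold changes here too, at 8.30 (interval 7.75 to 9.37) and 7.70 (7.31 to 8.28). AG00699.1 had the most negative one, at -9.44 (-10.37 to -8.91). AG07930.1 was lower by less, at -2.27 (-2.49 to -2.07). Scaling by total counts instead of TMM moved the median of all genes by -0.17 in this comparison and gave 633 genes lower and 101 higher.

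The salt difference at 36 h was then set against the salt differences at 84 h, which come from other libraries. The fold changes of 3 M against 1 M at 36 h correlated with those of 4 M against 0 M at 84 h at r = 0.769 (rho = 0.701, 6572 genes) and with those of 4 M against 3 M at 84 h at r = 0.805. With the same salt contrast at 84 h, 3 M against 1 M, the correlation was r = 0.265 (rho = 0.293, 6643 genes). With 3 M against 0 M at 84 h it was near 0 (r = 0.0548, rho = -0.0885, 6611 genes), and with 1 M against 0 M it was negative (r = -0.221, rho = -0.313, 6656 genes). Of the genes measured in both comparisons, 360 were 4-fold lower both in 3 M at 36 h and in 4 M against 0 M at 84 h, where independent lists would share 42, and 69 were higher in both, where independent lists would share 3.85. For 3 M against 1 M at both times, 113 genes were lower in both (16.9 for independent lists) and 23 higher in both (2.32 for independent lists).

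**Figure D4:**
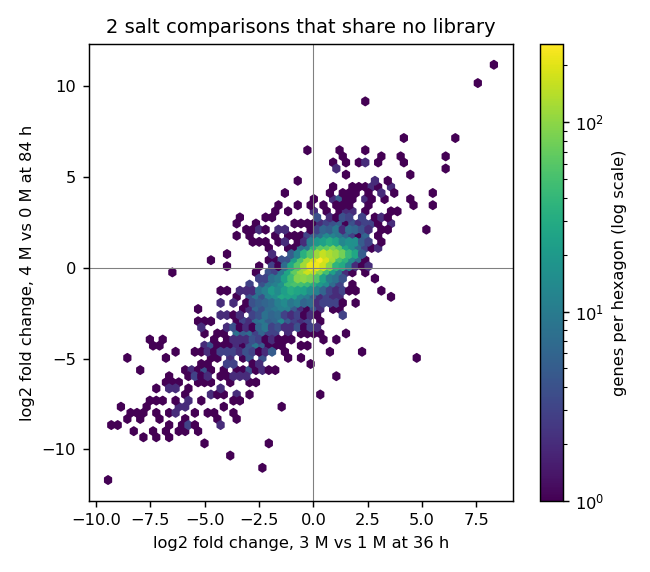
Log2 fold change of 3 M against 1 M NaCl at 36 h (x axis) and of 4 M against 0 M at 84 h (y axis) for the 6158 genes measured in both, with colour giving the number of genes per hexagon on a log scale. The points lie along the diagonal (r = 0.797 over these genes), with a longer arm toward lower expression on both axes.

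The genes 4-fold apart at 36 h were followed as groups through the 84 h libraries. The 559 genes lower in 3 M at 36 h had a median log2 fold change of -3.39 (95% interval over genes -3.60 to -3.17) in 4 M against 0 M at 84 h, and 405 of them were at least 4-fold lower there. In 3 M against 0 M at 84 h their median was -0.16 (-0.27 to 0.0044), with 69 at least 4-fold lower and 32 at least 4-fold higher. In 1 M against 0 M it was 0.34 (0.23 to 0.46). The 130 genes higher in 3 M at 36 h had a median of 2.12 (1.64 to 2.51) in 4 M against 0 M, with 70 at least 4-fold higher. In 3 M the median of these 130 genes was 0.25 (-0.18 to 0.69) against 0 M and 0.96 (0.72 to 1.24) against 1 M. In 1 M against 0 M it was -0.68 (-0.94 to -0.078), with 79 of the 130 below 0, so the 1 M library itself lay below 0 M for this group. In each of the 5 comparisons at 84 h, the medians of both groups lay outside all of the 10000 random lists matched on expression, in 1 M against 0 M in the direction opposite to that at 36 h. The lists were matched on mean expression and not on how much genes vary between libraries, and their genes were drawn independently. Lying outside them therefore does not tell these groups from other variable genes. The central 95% of random medians was -0.042 to 0.143 for the lower group in 4 M against 0 M, and -0.156 to 0.12 for the higher group in 3 M against 0 M.

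**Figure D5:**
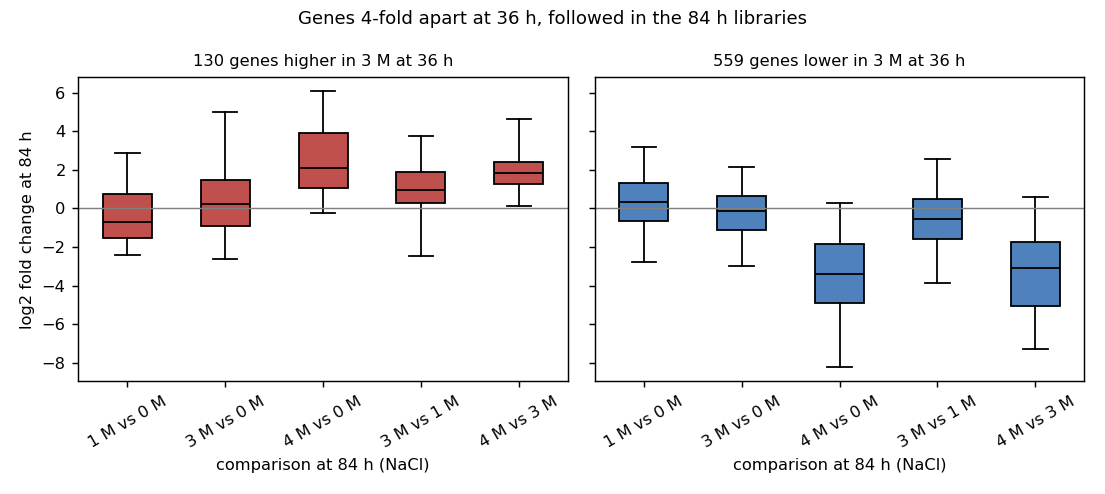
Log2 fold changes in the 5 comparisons at 84 h of the 130 genes at least 4-fold higher (left) and the 559 genes at least 4-fold lower (right) in 3 M than in 1 M at 36 h. Boxes give the median and quartiles over genes and whiskers the central 90%, and the medians in 4 M against 0 M are 2.12 and -3.39.

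Culture time was compared at each salt concentration that was sampled at both times. In 3 M, 528 genes were at least 4-fold higher and 224 at least 4-fold lower at 84 h than at 36 h, of 6320 compared. The higher genes took 1.22% of counts at 36 h and 15.1% at 84 h, and 73 of them were at least 64-fold higher. Lower genes made up 29.8% of the 4-fold genes with TMM scaling and 19.1% with scaling by total counts (626 higher, 148 lower), which moved the median of all genes by 0.22. In 1 M the difference was smaller and more even, with 245 genes higher and 184 lower at 84 h, of 6391 compared. The time differences in 1 M and in 3 M correlated at r = 0.273 (rho = 0.391, 6643 genes). Of the genes measured in both, 83 were higher at 84 h in 1 M and in 3 M, where independent lists would share 13.4, and 17 were lower in both, where independent lists would share 4.81.

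The time difference in 3 M ran opposite to the difference between 4 M and 0 M at 84 h, but not to that between 1 M and 0 M. Across 6567 genes the fold changes of 84 h against 36 h in 3 M correlated with those of 4 M against 0 M at 84 h at r = -0.613 (rho = -0.502), with no library shared. There were 299 genes at least 4-fold higher at 84 h than at 36 h in 3 M that were at least 4-fold lower in 4 M than in 0 M, where independent lists would share 37.1. In the opposite corner, 45 genes were lower with time in 3 M and higher in 4 M, where independent lists would share 6.3. With 1 M against 0 M at 84 h the correlation was positive (r = 0.274, rho = 0.402, 6671 genes), and 75 genes were higher in both, where independent lists would share 14.8. The other combinations exceeded independent lists too, with 32 genes lower in both (4.55 for independent lists). A further 18 were higher in 1 M and lower with time (6.03), and 22 lower in 1 M and higher with time (11.2). This overlap alone therefore gives no direction. AG00699.1 went from 1.05 CPM at 36 h to 112 CPM at 84 h in 3 M (log2 fold change 6.59, interval 6.05 to 7.52). AG04473.1 went from 293 to 6.11 CPM (-5.56, interval -5.86 to -5.32), and AG04474.1 from 469 to 26.7 CPM (-4.13, interval -4.27 to -4.01).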

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

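In this part, the comparison of the 2 most similar libraries was chosen only after the result was seen. The test of a wrong label and the test of culture stage had their predictions written first.

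Some genes differed between 3 M and 1 M NaCl in opposite directions at the 2 times. Between them, 46 genes were at least 4-fold lower in 3 M at 36 h and at least 4-fold higher in 3 M at 84 h, where independent lists would share 11.5, and 8 went the other way, where independent lists would share 3.4. Likewise, 33 genes were at least 4-fold lower at 84 h than at 36 h in 1 M but higher in 3 M (12.7 for independent lists), and 13 were higher with time in 1 M but lower in 3 M (5.09 for independent lists). Overlaps in the same direction exceeded independent lists as well. For 3 M against 1 M, 113 genes were lower at both times and 23 higher (16.9 and 2.32 for independent lists). For time, 83 genes were higher in both salt concentrations and 17 lower (13.4 and 4.81). The excess over independent lists therefore does not single out opposite changes. With 1 library per condition the differences between times and between salt concentrations were not tested.

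The 3 M culture at 36 h and the 4 M culture at 84 h lay close together and apart from the other 4 libraries, so that 3 M at 84 h resembled the cultures in less salt. The tables argue against 1 library deposited under 2 labels or mixed wholly into the other, since 140 genes differed at least 4-fold between the pair with counting intervals beyond 2-fold. A wrong label on the 3 M library at 84 h, for a culture in 0 M or 1 M, cannot be told apart from a true 3 M culture. The 130 genes higher in 3 M at 36 h had a median log2 fold change of 0.254 (-0.178 to 0.691 over genes) against 0 M and 0.962 (0.723 to 1.24) against 1 M. Against 0 M, 29 of them were at least 4-fold higher and 14 at least 4-fold lower. Against 1 M, 27 were at least 4-fold higher and 11 at least 4-fold lower. With 1 library per condition the spread between cultures in the same salt is unknown. AG04473.1 and AG04474.1 stood above 0 M by log2 fold changes of 4.19 and 4.69, the way the label says. Against 1 M at 84 h, a library not used to pick them, they stood above by 3.21 (interval 2.51 to 4.54) and 4.73 (4.18 to 5.71). These 2 genes were picked in 4 M as the furthest above the same 0 M library. How much single genes vary between cultures in the same salt is unknown, so these 2 do not decide the label. A biological candidate explanation is that cultures in high salt are at an earlier stage of growth. The time difference in 3 M (r = -0.613 with 4 M against 0 M) restates the pattern to be explained, so it cannot count in favour. The time difference in 1 M correlated with 4 M against 0 M at r = -0.0767 over 6668 genes. This was short of the -0.2 set beforehand as needed and above the -0.1 set as counting against the explanation. The margin to -0.1 was small. The interval was -0.101 to -0.0528, although it takes genes as independent, and a CPM minimum of 50 gave -0.102. The 4-fold genes of the time difference in 1 M overlapped those of 4 M against 0 M in opposite directions (64 and 11 genes, where independent lists would share 16.3 and 3.53). They overlapped as much in the same direction (66 and 10, against 14.2 and 4.08). An exchange of the labels of the 2 libraries in 3 M NaCl was not tested. By number of 4-fold genes, the library labelled 3 M at 36 h was closest to 4 M at 84 h (140 genes). The library labelled 3 M at 84 h was closest to 1 M at 36 h (276 genes). Such an exchange would reverse the time difference in 3 M and alter each comparison that uses a 3 M library. It stays open, as do growth stage, single cultures and batches that the labels do not give.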

How the results depend on the processing

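Of the counts of 4-fold genes in the 8 comparisons, all stayed within 1.5 times of the reported value with DESeq2 size factors, a prior count of 0.5, a counting interval wholly beyond 4-fold, and TMM factors from the 2 libraries compared, the last added after seeing the data. Scaling by total counts moved 1 of them beyond that, 84 h against 36 h in 3 M, from 224 to 148 lower genes, and no shared gene list was compared across settings. A 2-fold threshold gave, by construction, larger counts of higher and lower genes: 767 and 784 for 1 M against 0 M, 531 and 648 for 3 M against 0 M, 739 and 1183 for 4 M against 0 M, 598 and 667 for 3 M against 1 M at 84 h, 900 and 1099 for 4 M against 3 M, 855 and 1110 for 3 M against 1 M at 36 h, 758 and 646 for 84 h against 36 h in 1 M, and 1221 and 969 for the same in 3 M. It also gave 192 genes higher and 261 lower at every salt step. The split for 1 M against 0 M turned at 2-fold, and the cause was not tested. Without the low-count filter, more genes entered, and the counts that moved were 280 lower in 1 M against 0 M, 238 higher and 317 lower in 3 M against 0 M, 973 lower in 4 M against 0 M, 256 higher in 3 M against 1 M at 84 h, and 309 lower for 84 h against 36 h in 1 M. None of the 4 planned correlations changed sign. An unplanned one did, that of 3 M against 1 M at 36 h with 3 M against 0 M at 84 h (r = 0.0548, rho = -0.0885). Without the filter the 4 planned correlations, of 3 M against 1 M at both times, of time in 1 M with time in 3 M, of 3 M against 1 M at 36 h with 4 M against 0 M, and of the first with the last salt step, were 0.242, 0.238, 0.733 and -0.0946. Their Spearman's rho values were 0.293, 0.391, 0.701 and -0.273. A CPM minimum of 50 gave 0.300 for time in 1 M with time in 3 M and 0.812 for 3 M against 1 M at 36 h with 4 M against 0 M. In 4 M against 0 M at 84 h the fold changes of the 4 named genes stayed within their counting intervals under each alternative. In the other 7 comparisons, run after seeing the data with the other scalings and a prior count of 0.5, 6 of 84 values fell outside them, by shifts of at most 0.22, of which 5 came from total counts and 1 from DESeq2 size factors. The gene list medians planned under 4 alternatives were not run, since no ID matched a name. Leaving out a replicate was not possible with 1 library per condition. Replicates could not be paired, since the labels give no replicate numbers. A fit of salt blocked on time to the 4 libraries in 1 M and 3 M, with 1 residual degree of freedom, was possible but was not made. Depth limits only the low genes, since 3 counts correspond to at most 0.185 CPM, and the missing replicates limit every comparison.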

Other observations

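The counts per library in this paragraph, the runs of IDs in the next and the filter on the higher of 2 libraries in the last were chosen after the data were seen, while the other tests of explanations below had their predictions written before their results. The 1 M library at 84 h held the most genes of its own: 95 genes were at least 4-fold above each of the 5 other libraries and 16 at least 4-fold below, of 6745. The 4 M library at 84 h had the reverse balance, with 9 above and 77 below. In the 3 M library at 84 h the counts were 15 and 6, in 0 M at 84 h 35 and 15, in 1 M at 36 h 25 and 0, and in 3 M at 36 h 3 and 1. A gene that 2 libraries share counts for neither. This lowers the counts of 3 M at 36 h and 4 M at 84 h, the most alike pair (r = 0.946). The counts therefore do not rank how far the libraries lie apart. The most abundant transcript was AG06730.1 in all 6 libraries, with 1.44% to 2.08% of counts.

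Genes with neighbouring ID numbers had similar fold changes. In 4 M against 0 M at 84 h, directly adjacent IDs correlated at r = 0.277 (5117 pairs), 2 IDs apart at 0.125 and 5 IDs apart at 0.00364, where the central 95% of 1000 shuffles for adjacent IDs was -0.026 to 0.025. Runs of at least 4 consecutive IDs that were all at least 4-fold lower numbered 9, with 43 genes, and no run was higher, where shuffles gave 0.305 runs of either direction on average and 3 at most. In 3 M against 1 M at 36 h there were 5 such runs, all lower, and 3 of them shared at least 4 IDs with a run at 84 h, among them the run around AG07930.1. Correlations in that comparison at 5 and 50 IDs apart (0.0335 and 0.0316) lay slightly above the shuffles (upper limits 0.029 and 0.028). At 10 IDs apart the value lay within them (0.0137). In 4 M against 0 M, IDs 50 apart correlated at 0.0281, at the upper limit of 0.028. Weak correlation at long distance is therefore not excluded. Lower genes outnumbered higher ones in both comparisons, with 9.98% lower and 3.24% higher in 4 M against 0 M. Runs of higher IDs were thus less likely from the start, and their absence does not set lowered genes apart. Reads shared only between directly adjacent genes do not account for the whole pattern, since IDs 3 apart still correlated at 0.0818 (shuffles -0.027 to 0.029). Reads shared across several IDs, as among paralogs that could not be recognised, were not tested. Low counts do not account for the whole pattern either, since adjacent IDs among genes with a mean CPM of 50 or more correlated at 0.355. A hypothesis left open, if the IDs follow the order of the genome, is that clusters of neighbouring genes may be lowered together in high salt.

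More genes were 4-fold lower than higher in 4 M against 0 M at 84 h. The choice among the 3 scalings does not account for this. All log2 fold changes would have to shift by 0.75 to make the counts equal, while the 3 scalings differed by 0.098. Each scaling is relative to the library's own counts, so a change in total RNA between the cultures could not be seen and stays open. The low-count floor does not account for the whole excess of lower genes. Among 4171 genes with a CPM of 50 or more in the higher of the 2 libraries, 342 were lower and 136 higher, a ratio of 2.51. This filter treats both directions alike. A filter on the mean CPM over the 6 libraries gave 3.29 but keeps lower genes more readily, so it decides nothing. With 1 culture per condition, a difference between these cultures that is unrelated to salt stays open, and no biological explanation was tested.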
